A study of Mus musculus with 16 samples.

How the data were processed

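MEC1 mouse epicardial cells were profiled by RNA sequencing of poly(A)-enriched RNA, per the labels, in 16 libraries: 4 siRNA treatments (control, PRMT1, p53, both) without and with TGF-beta, 2 libraries per group. The series design calls the 2 libraries biological replicates without saying whether they come from separate cultures, and MEC1 is an established line, so a p-value here measures the spread between these libraries. TGF-beta dose and time, siRNA amounts, strand, annotation and counting options are not given. The deposited table holds expected counts per gene, which the authors made with TopHat2 and Partek on mm10 per their processing notes, with no versions; values were not scaled for library size or gene length. Of its 46348 genes, 29120 had a count, 60% of nonzero values lay within 0.01 of a whole number, and values were rounded to whole counts before testing. Library totals were 19617874 to 30759317.

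Groups came from the sample titles. A model with 1 mean per group was fitted to all 16 libraries with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, after TMM scaling and the filterByExpr filter, which kept 15494 genes. The common biological coefficient of variation was 0.114 with 16 libraries and 0.0604 with 15, and the prior degrees of freedom 3.41 and 6.64. There were 16 contrasts: the TGF-beta response under each siRNA treatment, each siRNA effect against control and on the other siRNA, without and with TGF-beta, and 4 interactions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Adjusted p-values in the text are from edgeR unless another tool is named.

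Gene lists, written from general knowledge before the data were examined, were tested with camera in limma 3.58.1 at a correlation of 0.01 and again with an estimated correlation, with at least 5 tested members and adjustment over lists within a contrast. The lists cover p53 target genes, p53 regulators and MDM family, TGF-beta early target genes, BMP-responsive Id genes, mesenchymal and EMT genes, epithelial junction and keratin genes, epicardial and mesothelial genes, smooth muscle contractile genes, fibroblast and collagen matrix genes and extracellular protease genes. They also cover S phase genes, G2/M phase genes, apoptosis regulators, senescence-associated secretory genes, interferon-stimulated genes, protein arginine methyltransferases, cholesterol synthesis genes, hypoxia and glycolysis genes, and unfolded protein and amino acid stress genes. Endothelial, cardiomyocyte and haematopoietic markers served as lists of other cell types. A list count "adjusted over the list alone" repeats the adjustment over its members. Of 320 list tests, 137 were called, and 58 of these kept the call with an estimated correlation; where a list given in the report did not, that p is printed beside it.

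Genes to name were set by a rule before the data were examined. It allows Prmt1, Trp53, Mdm4, Mdm2 and Cdkn1a; the 5 largest rises and falls per contrast (3 for interactions) among called genes with a mean of at least 5 CPM and no overlap between libraries; up to 4 members per list with the lowest adjusted p; and Acta2, Tagln, Cdh1, Tjp1, Snai1, Snai2, Wt1, Tbx18, Fn1 and Vim. Results of some genes that the rule allows are not reported. No fold is given against a group with 1 to 3 counts, and genes sharing reads with near copies were left out.

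Other settings set before the data were examined were DESeq2 1.42.0, RLE factors, no low-count filter, only the groups of the contrast, a replicate block, and leaving out each library of a contrast in turn. Leaving a library out leaves its group with 1, which is assumed to vary like the other groups. Chosen after seeing the data were a fit of 15 libraries, without replicate 2 of p53 siRNA with TGF-beta, and offsets that remove each library's smooth trend with transcript length, for 16 and 15 libraries. Transcript lengths came from GENCODE vM21, which may differ from the authors' annotation; 42003 genes matched by symbol and 814 by synonym.

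The procedure was tested on simulated data of the same size for the PRMT1 siRNA effect without TGF-beta. With libraries alike, edgeR recovered 55 of 67 genes changed by 0.5 (log2), 64 of 67 changed by 1 and 66 of 66 changed by 2, and called 9 unchanged genes. With 1 noisy library in another group it recovered 1, 33 and 64. A trend with transcript length in 3 libraries made it call 2825 unchanged genes, and 4 with length offsets.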

Results

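RNA was sequenced from MEC1, an established mouse epicardial cell line, in 8 groups of 2 libraries. The epicardium is the mesothelial layer that covers the heart, and in cultured epicardial cells TGF-beta drives the change from an epithelial to a mesenchymal state. Cells received control siRNA, PRMT1 siRNA, p53 siRNA or both of the last, each without and with TGF-beta. At 19617874 to 30759317 counts per library, 15494 genes passed the filter and were tested. The study's title names a pathway from PRMT1 through Mdm4 to p53 in epicardial invasion and cell fate, which sets the question of what each siRNA did to the TGF-beta response. Values in parentheses after a gene are log2 changes ± SE from edgeR with n = 2 libraries per group, and CPM are TMM-scaled and given as mean ± SD.

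TGF-beta separated the libraries most: the first principal component of the tested genes held 58.8% of the variance and split treated from untreated cells. The second component, 12.5%, set apart 1 library, replicate 2 of p53 siRNA with TGF-beta. Its root mean square log2 difference from its group partner was 0.805, against 0.341 to 0.426 in the other 7 groups, and its log2 CPM correlated with its partner's across genes at r = 0.9674, against 0.9901 or more, genes not being independent replicates. This library held 5.75% of its counts in Rn18s-rs5, a ribosomal RNA gene, against 0.557% to 4.35% elsewhere, and fewer detected genes than any other (19133). It was kept, although all groups share 1 estimate of the spread, and counts without it (15 libraries, chosen after seeing the data) are given where they differ by more than 1.5 times.

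**Figure D1:**
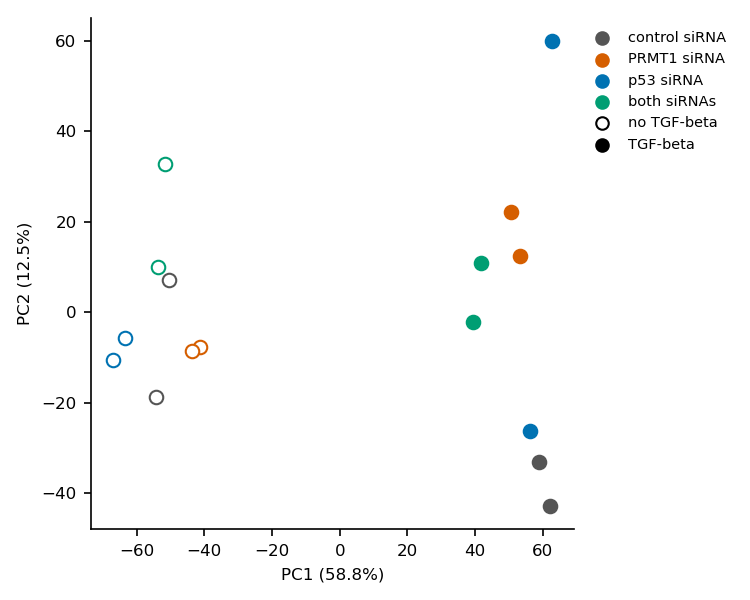
Scores of the 16 libraries on the first and second principal components of log2 CPM. Colour marks the siRNA, filled symbols TGF-beta; replicate 2 of p53 siRNA with TGF-beta lies apart from all others on the second axis.

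Both siRNA targets fell at the RNA level. Prmt1 (protein arginine methyltransferase 1, chromosome 7, 44975989 to 44986493, mm10) stood at 158 ± 21.2 CPM in untreated control cells and at 75.8 ± 1.85 CPM with PRMT1 siRNA, 48.1% of control. It was 47.6% with PRMT1 siRNA and TGF-beta, and 46.3% and 41.1% with both siRNAs without and with TGF-beta. Trp53 (p53, chromosome 11, 69580359 to 69591874) fell from 136 ± 11.5 to 54.8 ± 0.822 CPM with p53 siRNA, 40.2% of control, and was 48.7% with TGF-beta. With both siRNAs it was less reduced, at 89.4 ± 1.87 CPM (65.5%) without and 90.0 ± 0.419 CPM with TGF-beta. PRMT1 siRNA alone left Trp53 at 142 ± 0.588 CPM without TGF-beta (0.05 ± 0.09, adjusted p = 0.792) and raised it with TGF-beta (0.36 ± 0.09, adjusted p = 0.0251). That rise was 0.20 ± 0.04 with length offsets and 15 libraries, and its adjusted p ran from 0.106 to 0.132 without any 1 of the 4 libraries. Mdm4 (chromosome 1, 132959484 to 133030562), which encodes an inhibitor of p53, stood at 150.3 ± 18.8 CPM in control cells and 129.8 ± 3.74 CPM with PRMT1 siRNA (-0.21 ± 0.22, adjusted p = 0.636). With TGF-beta, PRMT1 siRNA lowered Mdm4 to 82.2 ± 1.40 CPM, against 143 ± 6.59 with control siRNA (-0.80 ± 0.23, adjusted p = 0.0361). Without any 1 of the 4 libraries the fall was -0.84 to -0.74 and not called. A length trend shared by a group would stay. The call held with length offsets and 15 libraries. Without PRMT1 siRNA Mdm4 was 144 and 73.3 CPM in replicates 1 and 2 of p53 siRNA with TGF-beta, which differ by length trend. Mdm2 (chromosome 10, 117688888 to 117710759), a ubiquitin ligase for p53 and itself a p53 target, rose with PRMT1 siRNA (0.61 ± 0.09) and fell with p53 siRNA (-0.41 ± 0.09). Cdkn1a (chromosome 17, 29090979 to 29100723), which encodes the cell cycle inhibitor p21, was 28.1 ± 1.30 CPM in control, 82.8 ± 4.66 with PRMT1 siRNA, 9.12 ± 0.120 with p53 siRNA and 37.1 ± 0.715 with both. With TGF-beta Cdkn1a stood at 55.4 ± 0.187, 105 ± 4.03, 23.8 ± 1.25 and 47.6 ± 0.180 CPM in the same order.

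**Figure D2:**
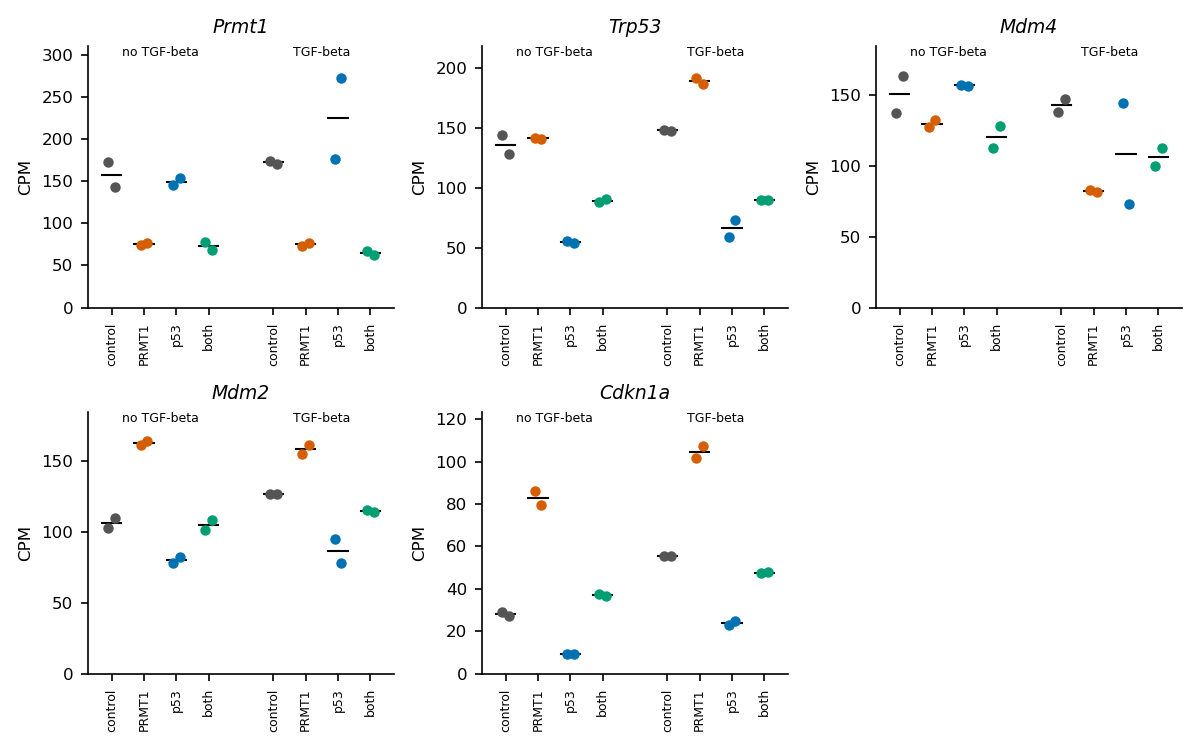
CPM (linear axis from 0) of Prmt1, Trp53, Mdm4, Mdm2 and Cdkn1a in each library of the 8 groups. Points are libraries and horizontal lines are means of 2; Cdkn1a was highest in PRMT1 siRNA with TGF-beta and lowest in p53 siRNA without it.

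With control siRNA, TGF-beta raised 2752 genes and lowered 3198, 858 and 1438 of them by 2-fold or more. The other TGF-beta responses are compared with this one. Of the TGF-beta early target genes, 21 of 25 tested rose and 2 fell (22 and 2 adjusted over the list alone, camera adjusted p = 7.37e-24). Ctgf, a secreted matrix-associated factor, went from 25.3 ± 1.02 to 499 ± 67.8 CPM (4.30 ± 0.12), and Pmepa1, a feedback inhibitor of the pathway, rose by 3.47 ± 0.10. Of the mesenchymal and EMT genes, 18 of 28 tested rose and 4 fell (18 and 5 adjusted over the list alone, camera adjusted p = 7.37e-09). They included the integrins Itgb3 (3.45 ± 0.17) and Itga5 (1.95 ± 0.08), the EMT transcription factors Snai1 (2.05 ± 0.14) and Snai2 (1.26 ± 0.11), fibronectin, Fn1 (1.40 ± 0.24), and vimentin, Vim (0.61 ± 0.15). Of the smooth muscle contractile genes, 17 of 21 tested rose and 2 fell (18 and 2 adjusted over the list alone, camera adjusted p = 1.23e-06). Acta2, smooth muscle alpha-actin, rose by 2.35 ± 0.20, Tagln, transgelin, from 115 ± 10.6 to 618 ± 41.0 CPM (2.43 ± 0.20) and Cnn1, calponin, by 2.91 ± 0.27. Fibroblast and collagen matrix genes moved both ways: 15 of 30 tested rose and 9 fell (15 and 9 adjusted over the list alone, camera adjusted p = 0.274). Postn, periostin, rose from 33.4 ± 0.928 to 769 ± 55.2 CPM (4.53 ± 0.10), whereas the proteoglycan gene Dcn (-4.43 ± 0.15) and the collagen VI genes Col6a1 (-2.81 ± 0.08) and Col6a2 (-3.42 ± 0.10) fell. Among the extracellular protease genes, 11 of 29 tested rose and 6 fell (11 and 7 adjusted over the list alone, camera adjusted p = 0.00687, adjusted p = 0.0597 with an estimated correlation), with a median log2 change of -0.03 and a mean of 0.22. Mmp9 (5.35 ± 0.15) and Mmp2 (2.32 ± 0.08), both gelatinases, rose and the collagenase gene Mmp13 fell (-4.17 ± 0.21). Adjusted p for the genes given here as changed was 0.0075 or less.

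The genes that mark epicardium fell together in the same cells. Of the epicardial and mesothelial genes, 21 of 25 tested fell and 2 rose (21 and 3 adjusted over the list alone, camera adjusted p = 6.25e-37). Upk3b, a mesothelial membrane protein, went from 574 ± 17.7 to 24.3 ± 0.734 CPM (-4.56 ± 0.13), and Gpm6a (-6.18 ± 0.12), the retinaldehyde dehydrogenase gene Aldh1a1 (-3.02 ± 0.09) and the transcription factor genes Gata6 (-2.62 ± 0.06) and Wt1 (-1.22 ± 0.10) fell. Tbx18, another epicardial transcription factor gene, did not pass the test (0.28 ± 0.11, adjusted p = 0.0624). Of the epithelial junction and keratin genes, 10 of 20 tested fell and 4 rose (11 and 4 adjusted over the list alone, camera adjusted p = 0.00482, adjusted p = 0.0597 with an estimated correlation). Krt7, a keratin (-3.93 ± 0.15), Cgn, cingulin of tight junctions (-2.05 ± 0.09), and the claudin gene Cldn15 (-5.22 ± 0.26) fell, and the tight junction scaffold gene Tjp1 gave 0.09 ± 0.26, adjusted p = 0.82. Cdh1, E-cadherin, was at or near the floor in all 8 groups (0.0926 ± 0.00584 CPM in control) and was not tested. BMP-responsive Id genes fell: 6 of 7 tested fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.000209, adjusted p = 0.199 with an estimated correlation), among them Id2 (-3.36 ± 0.17) and Id3 (-1.76 ± 0.19), inhibitors of basic helix-loop-helix factors. Of the interferon-stimulated genes, 29 of 32 tested fell (30 adjusted over the list alone, camera adjusted p = 1.84e-11, adjusted p = 0.191 with an estimated correlation), Mx1 (-2.43 ± 0.14) and Rsad2 (-1.33 ± 0.14), both antiviral effectors. Cholesterol synthesis genes rose: 16 of 23 tested rose (17 adjusted over the list alone, camera adjusted p = 8.78e-08). Members included Cyp51 (1.38 ± 0.07), a sterol demethylase. Of the unfolded protein and amino acid stress genes, 18 of 28 tested rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 0.000279, adjusted p = 0.405 with an estimated correlation). Members included Cth (2.20 ± 0.15), an enzyme of cysteine synthesis, and the amino acid transporter gene Slc7a5 (0.91 ± 0.08). The S phase genes (13 of 30 tested rose and 2 fell, 14 and 2 adjusted over the list alone, camera adjusted p = 0.0367, adjusted p = 0.501 with an estimated correlation) and the G2/M phase genes (11 of 31 tested rose and 1 fell, 11 and 1 adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.393 with an estimated correlation) moved less, by medians of 0.20 and 0.18. The p53 target genes went both ways (15 of 42 tested rose and 9 fell, 15 and 12 adjusted over the list alone, camera adjusted p = 0.518), Cdkn1a rising by 0.98 ± 0.07 and the stress-response gene Sesn1 falling (-1.82 ± 0.10). Outside the lists, the engulfment receptor gene Megf10 rose from 0.209 ± 0.0459 to 66.4 ± 5.18 CPM (8.28 ± 0.34) and Saa3, a serum amyloid A, fell from 87.6 ± 13.9 to 0.421 ± 0.176 CPM (-7.73 ± 0.34). Adjusted p was at most 1.88e-05 for the genes given as changed. Of the 39 genes named as changed, 38 kept the call without any 1 library of the comparison, Vim being the exception.

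**Figure D3:**
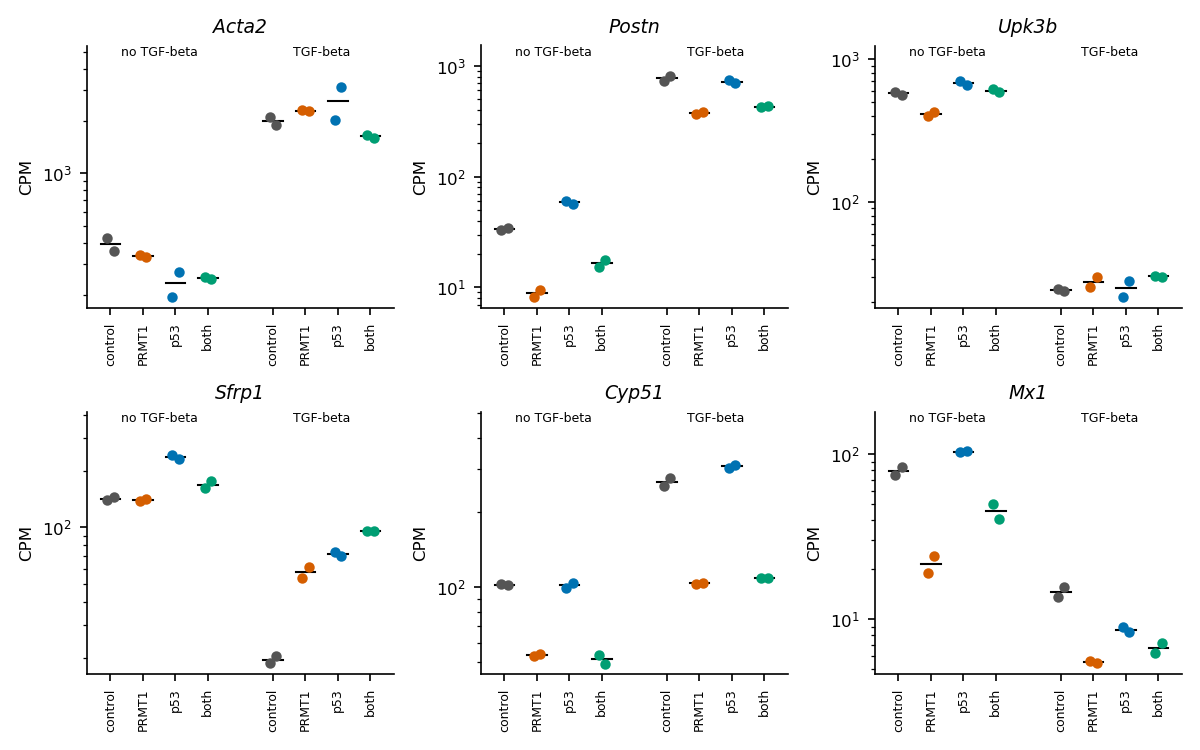
CPM (log axis) of Acta2, Postn, Upk3b, Sfrp1, Cyp51 and Mx1 in each of the 16 libraries. Points are libraries and lines are group means; Acta2 and Postn were higher and Upk3b lower with TGF-beta under all 4 siRNA treatments.

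Under PRMT1 siRNA, TGF-beta raised 2530 genes and lowered 2505. Of the 5950 genes called in control cells, 5488 (92.2%) moved the same way here, at a median ratio of log2 changes of 0.64, against 52.8% of genes not called. TGF-beta early target genes (21 of 25 tested rose, 21 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.6e-28), smooth muscle contractile genes (16 of 21 tested rose and 1 fell, 17 and 1 adjusted over the list alone, camera adjusted p = 3.73e-10) and mesenchymal and EMT genes (14 of 28 tested rose and 2 fell, 15 and 2 adjusted over the list alone, camera adjusted p = 1.9e-09) rose. Pmepa1 rose by 3.98 ± 0.10, Acta2 by 2.77 ± 0.20, Tagln by 2.81 ± 0.20 and Snai1 by 2.14 ± 0.14. Fn1 did not pass the test (0.65 ± 0.24, adjusted p = 0.0589). Among the epicardial and mesothelial genes, 17 of 25 tested fell and 3 rose (18 and 3 adjusted over the list alone, camera adjusted p = 2.9e-31). Members included Upk3b (-3.89 ± 0.12), Gata6 (-1.87 ± 0.06), Aldh1a1 (-2.92 ± 0.09) and Wt1 (-1.02 ± 0.10). Postn rose from 8.88 ± 0.859 to 378 ± 10.8 CPM (5.41 ± 0.11), Mmp14, a membrane-anchored matrix protease, by 1.91 ± 0.07 and Il6, a cytokine, by 1.73 ± 0.12. Of the cholesterol synthesis genes, 9 of 23 tested rose and 3 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0503), and of the interferon-stimulated genes, 21 of 32 tested fell and 1 rose (21 and 1 adjusted over the list alone, camera adjusted p = 9.16e-06, adjusted p = 0.392 with an estimated correlation). Cyp51 rose by 0.96 ± 0.07 and Mx1 fell (-1.97 ± 0.15). Of the p53 target genes, 12 of 42 tested fell and 11 rose (12 and 11 adjusted over the list alone, camera adjusted p = 0.936). Cdkn1a rose by 0.34 ± 0.07, Trp53 by 0.42 ± 0.09 and Cdkn2a, which encodes p16Ink4a and p19Arf, by 2.57 ± 0.23, and Mdm4 fell (-0.66 ± 0.23). Genes given as changed had adjusted p of 0.0429 or less. Leaving out any 1 of the 4 libraries lowered the count of called genes from 5035 to 3228 and 3080 without replicates 1 and 2 of the untreated group and to 3143 and 3211 without replicates 1 and 2 of the TGF-beta group, and 15 libraries gave 8150. Of the 17 genes named as changed, 14 kept the call without any 1 library of the comparison, Cdkn1a, Mdm4 and Trp53 being the exceptions.

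Under p53 siRNA the response was of the same kind, with 3604 genes higher and 3408 lower, and 5708 of 5950 (95.9%) keeping the sign seen in control cells at a median ratio of 0.94, against 57.3% of genes not called. The comparison asks whether TGF-beta acts when p53 is reduced. Of the TGF-beta early target genes, 19 of 25 tested rose and 3 fell (20 and 3 adjusted over the list alone, camera adjusted p = 5.85e-17). Members included Pmepa1 at 3.81 ± 0.10, Ctgf at 3.80 ± 0.12 and Tgfbi, a secreted adhesion protein, at 3.10 ± 0.10. Smooth muscle contractile genes rose (17 of 21 tested rose and 2 fell, 17 and 2 adjusted over the list alone, camera adjusted p = 1.24e-07), Acta2 by 3.47 ± 0.21 and Tagln by 3.37 ± 0.20. Of the mesenchymal and EMT genes, 17 of 28 tested rose and 4 fell (17 and 4 adjusted over the list alone, camera adjusted p = 1.21e-06). Members included Snai1 at 2.57 ± 0.14 and Pdgfrb, a platelet-derived growth factor receptor gene, at 1.94 ± 0.10. Epicardial and mesothelial genes fell (21 of 25 tested fell and 1 rose, 21 and 3 adjusted over the list alone, camera adjusted p = 7.44e-34), Gpm6a (-7.19 ± 0.13), Upk3b (-4.77 ± 0.13) and Wt1 (-1.17 ± 0.10). Among the interferon-stimulated genes, 31 of 32 tested fell and 1 rose (31 and 1 adjusted over the list alone, camera adjusted p = 3.01e-21, adjusted p = 0.0614 with an estimated correlation). Mx1 (-3.58 ± 0.15), Rsad2 (-2.76 ± 0.14) and Oas2 (-3.81 ± 0.22), an RNA sensor, were 3 of the members that fell. Of the G2/M phase genes, 22 of 31 tested rose (26 adjusted over the list alone, camera adjusted p = 1.88e-05). Members included the mitotic kinase gene Aurka (1.10 ± 0.10) and the spindle genes Kif23 (0.96 ± 0.09) and Tpx2 (0.75 ± 0.06). Of the unfolded protein and amino acid stress genes, 21 of 28 tested rose (21 adjusted over the list alone, camera adjusted p = 1.48e-07, adjusted p = 0.179 with an estimated correlation). Members included Asns, asparagine synthetase, at 1.56 ± 0.12 and Mthfd2, a mitochondrial folate enzyme, at 1.87 ± 0.12. Cdkn1a rose from 9.12 ± 0.120 to 23.8 ± 1.25 CPM (1.38 ± 0.08). No adjusted p above 4.32e-06 belongs to a gene given as changed, and the library that stands apart is in this group. Other single libraries kept the count within 1.5 times of 7012, and without it 7431 genes were called, 5773 of them shared. Of the 23 genes named as changed, 22 kept the call without any 1 library of the comparison, Prmt1 being the exception.

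With both siRNAs, TGF-beta raised 2324 genes and lowered 2527, and 5826 of 5950 (97.9%) kept the sign of control cells at a median ratio of 0.75, against 74.7% of genes not called. TGF-beta early targets (21 of 25 tested rose and 2 fell, 21 and 2 adjusted over the list alone, camera adjusted p = 1.82e-18) and smooth muscle contractile genes (18 of 21 tested rose and 1 fell, 18 and 1 adjusted over the list alone, camera adjusted p = 1.43e-09) rose, Pmepa1 by 3.23 ± 0.10, Acta2 by 2.70 ± 0.20 and Tagln by 2.60 ± 0.20. Of the mesenchymal and EMT genes, 17 of 28 tested rose and 3 fell (17 and 4 adjusted over the list alone, camera adjusted p = 1.61e-10). Members included Snai1 at 1.67 ± 0.14, Fn1 at 1.40 ± 0.24 and Itga5 at 1.78 ± 0.08. Postn rose by 4.71 ± 0.10 and Col5a1, a fibrillar collagen gene, by 2.44 ± 0.10. Epicardial and mesothelial genes fell (18 of 25 tested fell and 2 rose, 20 and 3 adjusted over the list alone, camera adjusted p = 3.79e-33), Upk3b (-4.31 ± 0.12), Gata6 (-1.79 ± 0.06) and Wt1 (-1.09 ± 0.10). The epithelial junction and keratin genes fell as well (12 of 20 tested fell and 3 rose, 13 and 3 adjusted over the list alone, camera adjusted p = 3.69e-05), Krt7 (-3.81 ± 0.14), as did BMP-responsive Id genes (6 of 7 tested fell and 1 rose, 6 and 1 adjusted over the list alone, camera adjusted p = 1.19e-10), Id3 (-3.05 ± 0.20). Of the interferon-stimulated genes, 30 of 32 tested fell (31 adjusted over the list alone, camera adjusted p = 3.47e-13, adjusted p = 0.129 with an estimated correlation). Members included Mx1 at -2.75 ± 0.14, and of the cholesterol synthesis genes, 10 of 23 tested rose (10 adjusted over the list alone, camera adjusted p = 0.0131). Members included Cyp51 at 1.08 ± 0.07. Cdkn1a rose by 0.36 ± 0.07, and Trp53 and Mdm4 gave 0.01 ± 0.09, adjusted p = 0.947 and -0.17 ± 0.22, adjusted p = 0.602. Every gene given as changed passed at an adjusted p of 0.00203 or less. Without replicate 2 of both siRNAs with TGF-beta, 3172 genes were called in place of 4851, and 15 libraries gave 7639. All 16 genes named as changed in this comparison kept their call whichever of its libraries was left out.

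In cells without TGF-beta, PRMT1 siRNA raised p53 target genes and lowered interferon, cholesterol and matrix genes. It raised 694 genes and lowered 907. Of the p53 target genes, 19 of 42 tested rose and 3 fell (22 and 5 adjusted over the list alone, camera adjusted p = 1.44e-12). Cdkn1a rose from 28.1 ± 1.30 to 82.8 ± 4.66 CPM (1.56 ± 0.07), Pmaip1, which encodes the pro-apoptotic protein Noxa, from 7.09 ± 0.578 to 27.1 ± 1.88 CPM (1.94 ± 0.13), Zmat3, an RNA-binding protein, by 0.94 ± 0.11, Ccng1, cyclin G1, by 0.69 ± 0.08 and Mdm2 by 0.61 ± 0.09. The death receptor genes Tnfrsf10b (0.61 ± 0.11) and Fas (0.57 ± 0.14) rose. Among the interferon-stimulated genes, 27 of 32 tested fell (31 adjusted over the list alone, camera adjusted p = 1.69e-40). Mx1 fell (-1.88 ± 0.13), Rsad2 (-1.51 ± 0.14), Ifit2 (-1.45 ± 0.14) and the chemokine gene Cxcl10 from 951 ± 0.565 to 322 ± 52.2 CPM (-1.56 ± 0.15). Among the cholesterol synthesis genes, 12 of 23 tested fell (17 adjusted over the list alone, camera adjusted p = 5.32e-19). Members included Cyp51 at -0.94 ± 0.07, Insig1, a sterol sensor, at -1.06 ± 0.10 and Srebf2, the master regulator of the pathway, at -0.67 ± 0.07. Of the fibroblast and collagen matrix genes, 15 of 30 tested fell (16 adjusted over the list alone, camera adjusted p = 4.25e-14). Postn fell from 33.4 ± 0.928 to 8.88 ± 0.859 CPM (-1.91 ± 0.10), Fmod, fibromodulin, (-1.04 ± 0.08), Ogn, osteoglycin, (-0.72 ± 0.06) and Col6a1 (-0.57 ± 0.07).

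Epithelial junction and keratin genes also fell in these cells. Of these genes, 6 of 20 tested fell (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000775). Members included Jup, plakoglobin (-0.74 ± 0.09), Krt7 (-0.72 ± 0.12) and the junction adhesion gene F11r (-0.46 ± 0.08). Of the epicardial and mesothelial genes, 4 of 25 tested fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.0511). Members included Lrrn4 (-0.89 ± 0.13), Aldh1a1 (-0.48 ± 0.08) and Upk3b (-0.48 ± 0.11), while Tbx18 rose (0.49 ± 0.11) and Wt1 gave 0.06 ± 0.09, adjusted p = 0.764. Of the TGF-beta early targets, 4 of 25 tested rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.0545 with an estimated correlation). Members included Cyr61 at 0.80 ± 0.10. Acta2 (-0.22 ± 0.19, adjusted p = 0.548), Tagln (-0.11 ± 0.19, adjusted p = 0.79) and Snai1 (0.22 ± 0.14, adjusted p = 0.398) did not pass the test. Among the G2/M phase genes, 6 of 31 tested rose (9 adjusted over the list alone, camera adjusted p = 0.000259, adjusted p = 0.101 with an estimated correlation). Members included Nusap1, a spindle protein gene, at 0.40 ± 0.07 and Tpx2 at 0.33 ± 0.06. Among the senescence-associated secretory genes, 5 of 21 tested rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.16 with an estimated correlation), Cxcl1 and Cxcl5, neutrophil chemokines, rising by 0.93 ± 0.10 and 0.96 ± 0.14. Ptgs2, cyclooxygenase 2, rose from 25.2 ± 1.23 to 88.6 ± 0.251 CPM (1.82 ± 0.16), Lama4, a laminin chain, rose by 2.25 ± 0.20, and Tnnt2, a cardiac troponin gene, fell (-3.10 ± 0.26). Adjusted p was at most 0.0168 for the genes given as changed. Leaving out any 1 of the 4 libraries lowered the count from 1601 to 556 and 523 without replicates 1 and 2 of the control group and to 397 and 516 without replicates 1 and 2 of the group with PRMT1 siRNA, and 15 libraries raised it to 4259. Of the 33 genes named as changed, 24 kept the call without any 1 library of the comparison, Aldh1a1, F11r, Fas, Krt7, Nusap1, Tbx18, Tnfrsf10b, Tpx2 and Upk3b being the exceptions.

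In the presence of TGF-beta, PRMT1 siRNA again raised p53 target genes and lowered cholesterol and some interferon genes, and it held some epicardial genes above their level in control cells. It raised 1415 genes and lowered 1012. Among the p53 target genes, 15 of 42 tested rose (19 rose and 1 fell adjusted over the list alone, camera adjusted p = 7.58e-06). Members included Pmaip1 at 1.40 ± 0.13, Cdkn1a at 0.92 ± 0.07, Ei24 at 0.71 ± 0.08 and Ccng1 at 0.43 ± 0.08. Of the cholesterol synthesis genes, 18 of 23 tested fell (20 adjusted over the list alone, camera adjusted p = 1.51e-53). Idi1 fell from 66.3 ± 2.79 to 21.9 ± 0.159 CPM (-1.60 ± 0.07) and Cyp51 (-1.36 ± 0.07). Of the unfolded protein and amino acid stress genes, 11 of 28 tested fell and 1 rose (14 and 2 adjusted over the list alone, camera adjusted p = 2.11e-06, adjusted p = 0.322 with an estimated correlation), among them the serine synthesis gene Psat1 (-0.95 ± 0.08) and the transporter genes Slc7a5 (-0.71 ± 0.08) and Slc7a11 (-1.05 ± 0.18). Of the interferon-stimulated genes, 14 of 32 tested fell (17 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.89e-08, adjusted p = 0.322 with an estimated correlation). Members included Cmpk2 at -1.37 ± 0.12 and Mx1 at -1.42 ± 0.15. Among the epicardial and mesothelial genes, 8 of 25 tested rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 6.32e-05). Sfrp1, a secreted Wnt modulator, was 57.6 ± 5.38 CPM against 19.6 ± 1.21 (1.55 ± 0.09), complement C3 rose by 1.40 ± 0.11, and the cardiac transcription factor genes Gata4 and Gata6 rose by 0.81 ± 0.08 and 0.72 ± 0.06. Of the senescence-associated secretory genes, 9 of 21 tested rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 1.64e-06). Members included Cxcl5 at 2.51 ± 0.16, Igfbp3, a growth factor binding protein, at 1.41 ± 0.10 and the chemokine Ccl2 at 1.01 ± 0.15. Mesenchymal and EMT genes split (4 of 28 tested fell and 2 rose, 4 and 2 adjusted over the list alone, camera adjusted p = 0.315), Mmp14 rising by 0.50 ± 0.06 and Itgb3 (-0.81 ± 0.15), the matrix cross-linking gene Loxl2 (-0.63 ± 0.13) and Snai2 (-0.41 ± 0.11) falling. Among the fibroblast and collagen matrix genes, 6 of 30 tested fell and 3 rose (10 and 5 adjusted over the list alone, camera adjusted p = 0.0635), Postn (-1.02 ± 0.09) and Col1a2 (-0.37 ± 0.08), while Dcn rose by 1.02 ± 0.14. Acta2 (0.20 ± 0.19, adjusted p = 0.48), Tagln (0.27 ± 0.19, adjusted p = 0.325), Snai1 (0.30 ± 0.13, adjusted p = 0.127) and Wt1 (0.26 ± 0.10, adjusted p = 0.0796) did not pass the test. Saa3 rose from 0.421 ± 0.176 to 26.7 ± 3.44 CPM (6.02 ± 0.35) and Clu, clusterin, from 2.78 ± 0.619 to 27.9 ± 4.08 CPM (3.31 ± 0.21). Genes given as changed had adjusted p of 0.0263 or less. Leaving out any 1 of the 4 libraries lowered the count from 2427 to 747 and 797 without replicates 1 and 2 of the control group and to 729 and 692 without replicates 1 and 2 of the group with PRMT1 siRNA, and 15 libraries gave 6659. Log2 changes in this contrast correlated with transcript length across genes (Spearman's rho -0.36). Of the 29 genes named as changed, 22 kept the call without any 1 library of the comparison, Ccng1, Col1a2, Itgb3, Loxl2, Mdm4, Snai2 and Trp53 being the exceptions.

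**Figure D4:**
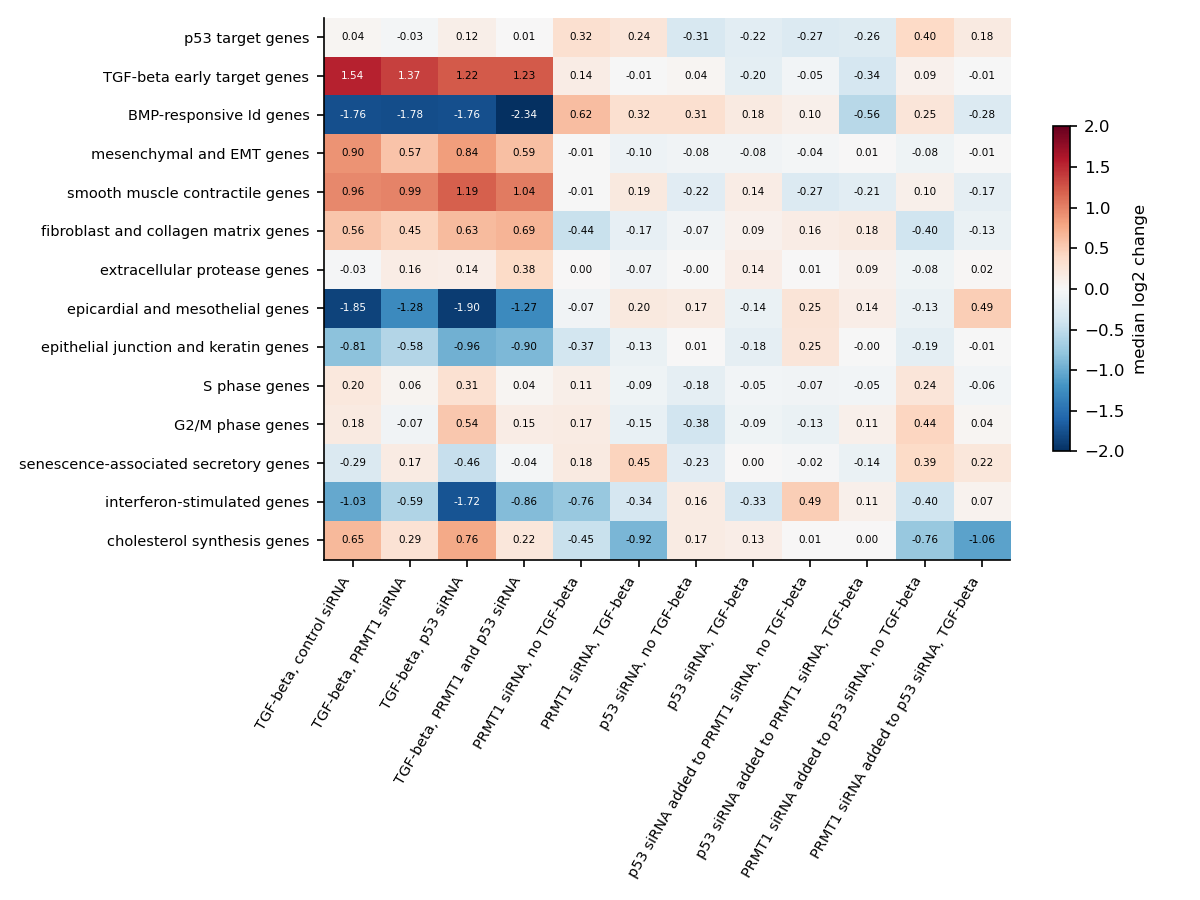
Median log2 change over the tested members of 14 gene lists (vertical) in the 12 TGF-beta and siRNA contrasts (horizontal), red for higher and blue for lower. Interferon-stimulated and epicardial and mesothelial genes had negative medians in all 4 TGF-beta responses, and cholesterol synthesis genes in all 4 PRMT1 siRNA contrasts.

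Without TGF-beta, p53 siRNA lowered p53 target and cell division genes and raised some matrix and epicardial genes. In total 182 genes were higher and 200 lower. Of the p53 target genes, 12 of 42 tested fell (17 fell and 1 rose adjusted over the list alone, camera adjusted p = 3.53e-19). Cdkn1a fell from 28.1 ± 1.30 to 9.12 ± 0.120 CPM (-1.62 ± 0.08), Sulf2, a heparan sulfate sulfatase, (-0.93 ± 0.09), Ephx1, epoxide hydrolase, (-0.85 ± 0.11), Ccng1 (-0.73 ± 0.08) and Mdm2 (-0.41 ± 0.09). Of the G2/M phase genes, 13 of 31 tested fell (26 adjusted over the list alone, camera adjusted p = 4.52e-26). Ccna2, cyclin A2, fell (-0.44 ± 0.06), Ccnb1, cyclin B1, (-0.38 ± 0.07), the kinase gene Nek2 (-0.52 ± 0.09) and Tpx2 (-0.42 ± 0.06). Of the S phase genes, 2 of 30 tested fell (8 adjusted over the list alone, camera adjusted p = 3.56e-06, adjusted p = 0.176 with an estimated correlation), among them Rrm2 (-0.41 ± 0.08). Of the fibroblast and collagen matrix genes, 6 of 30 tested rose (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.176 with an estimated correlation), with a median log2 change of -0.07 and a mean of 0.18, among them Lum, lumican (1.78 ± 0.21), Postn (0.81 ± 0.09) and Col6a1 (0.38 ± 0.07). Of the epicardial and mesothelial genes, 4 of 25 tested rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.000343). Members included Sfrp1 at 0.74 ± 0.08, Podxl, podocalyxin, at 0.84 ± 0.15 and Gata4 at 0.41 ± 0.08. Of the unfolded protein and amino acid stress genes, 4 of 28 tested fell (11 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.65e-08, adjusted p = 0.176 with an estimated correlation). Members included Slc7a5 at -0.55 ± 0.08 and Asns at -0.54 ± 0.12. Tagln fell (-0.85 ± 0.19) and Acta2 gave -0.74 ± 0.19, adjusted p = 0.0696. Cxcl1 fell (-0.72 ± 0.10), and Mgp, a calcification inhibitor, rose by 1.69 ± 0.25. Prmt1 (-0.08 ± 0.16, adjusted p = 0.905) and Mdm4 (0.06 ± 0.22, adjusted p = 0.956) did not pass the test. No adjusted p above 0.0411 belongs to a gene given as changed. Leaving out any 1 of the 4 libraries lowered the count from 382 to 55 and 102 without replicates 1 and 2 of the control group and to 58 and 127 without replicates 1 and 2 of the group with p53 siRNA, and 15 libraries raised it to 1877. Of the 21 genes named as changed, 6 kept the call without any 1 library of the comparison, Asns, Ccna2, Ccnb1, Col6a1, Cxcl1, Ephx1, Gata4, Mdm2, Mgp, Nek2, Podxl, Rrm2, Slc7a5, Tagln and Tpx2 being the exceptions.

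With TGF-beta, p53 siRNA lowered p53 target and some interferon genes and moved epicardial and secreted genes both ways, 437 genes being higher and 371 lower. Among the p53 target genes, 13 of 42 tested fell (18 fell and 5 rose adjusted over the list alone, camera adjusted p = 1.46e-06). Members included Cdkn1a at -1.22 ± 0.07, Ccng1 at -0.82 ± 0.08, Eda2r, a receptor gene, at -1.53 ± 0.19 and Mdm2 at -0.55 ± 0.09. Among the interferon-stimulated genes, 10 of 32 tested fell (15 fell and 1 rose adjusted over the list alone, camera adjusted p = 5.62e-11, adjusted p = 0.426 with an estimated correlation). Members included Rsad2 at -1.25 ± 0.14 and Cmpk2 at -1.15 ± 0.12. TGF-beta early target genes split (5 of 25 tested fell and 4 rose, 10 and 5 adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.0804 with an estimated correlation), Ctgf falling (-0.79 ± 0.10) and Hbegf, a growth factor, (-1.17 ± 0.13), and Tgfbi rising by 0.96 ± 0.09. Epicardial and mesothelial genes split as well (6 of 25 tested rose and 5 fell, 9 and 7 adjusted over the list alone, camera adjusted p = 0.727), Sfrp1 rising from 19.6 ± 1.21 to 72.1 ± 2.34 CPM (1.88 ± 0.09) and Msln, mesothelin, falling (-1.26 ± 0.12). Of the senescence-associated secretory genes, 5 of 21 tested fell and 4 rose (5 and 5 adjusted over the list alone, camera adjusted p = 0.863), Cxcl5 rising by 1.51 ± 0.15 and Ereg, an epidermal growth factor family member, falling (-1.10 ± 0.15). The imprinted noncoding RNA H19 rose from 29.7 ± 0.677 to 124 ± 23.3 CPM (2.06 ± 0.12) and Pappa, a secreted metalloprotease, fell (-1.81 ± 0.30). Acta2 (0.37 ± 0.19, adjusted p = 0.208) and Snai1 (0.25 ± 0.13, adjusted p = 0.216) did not pass the test (0.02 and -0.02 without the library that stands apart), and the largest adjusted p among changed genes was 0.00672. This contrast holds the library that stands apart, and its log2 changes correlated with transcript length across genes (rho -0.47). Without that library 661 genes were called, 447 shared with the 808, against 8622 without its partner and 148 and 212 without control replicates 1 and 2. Of the 15 genes named as changed, 13 kept the call without any 1 library of the comparison, Mdm2 and Pappa being the exceptions.

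Adding p53 siRNA to PRMT1 siRNA, without TGF-beta, raised 88 genes and lowered 46. Of the p53 target genes, 9 of 42 tested fell (19 fell and 3 rose adjusted over the list alone, camera adjusted p = 4.8e-15). Members included Cdkn1a falling from 82.8 ± 4.66 to 37.1 ± 0.715 CPM (-1.16 ± 0.07), Pmaip1 (-0.85 ± 0.12), Mdm2 (-0.63 ± 0.09) and Aen, an apoptosis-linked nuclease, (-0.56 ± 0.08). Of the interferon-stimulated genes, 2 of 32 tested rose (27 adjusted over the list alone, camera adjusted p = 8.35e-22, adjusted p = 0.0876 with an estimated correlation), Mx1 by 1.06 ± 0.13 and Irf7, an interferon transcription factor gene, by 0.78 ± 0.16. Krt7 rose by 0.88 ± 0.12, Upk3b by 0.55 ± 0.11 (of the epicardial and mesothelial genes, 1 of 25 tested rose, 11 rose and 2 fell adjusted over the list alone, camera adjusted p = 8.53e-05), Postn by 0.89 ± 0.10 and Fmod by 0.46 ± 0.08. Of the genes called for p53 siRNA alone, 345 of 382 (90.3%) moved the same way on the PRMT1 siRNA background, at a median ratio of 0.46, against 51.8% of genes not called. Every gene given as changed passed at an adjusted p of 0.0476 or less. The count of 134 fell to 4 and 7 without replicates 1 and 2 of the group with PRMT1 siRNA and to 6 and 9 without replicates 1 and 2 of the group with both siRNAs, but was 3482 with 15 libraries. The log2 changes correlated with transcript length across genes (rho -0.41). Of the 10 genes named as changed, 1 kept the call without any 1 library of the comparison, Aen, Fmod, Irf7, Krt7, Mdm2, Mx1, Pmaip1, Postn and Upk3b being the exceptions.

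With TGF-beta, adding p53 siRNA to PRMT1 siRNA lowered p53 targets and early TGF-beta targets, 34 genes being higher and 36 lower. Among the p53 target genes, 6 of 42 tested fell (18 fell and 2 rose adjusted over the list alone, camera adjusted p = 5.22e-15), Cdkn1a (-1.14 ± 0.07), the antiproliferative gene Btg2 (-0.56 ± 0.07) and Mdm2 (-0.47 ± 0.09). Of the TGF-beta early target genes, 7 of 25 tested fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 8.09e-15), Ctgf from 430.1 ± 31.3 to 207 ± 14.6 CPM (-1.06 ± 0.10), Smad7, the inhibitory Smad, (-0.59 ± 0.09) and Pmepa1 (-0.62 ± 0.09). Sfrp1 rose by 0.73 ± 0.08 (of the epicardial and mesothelial genes, 3 of 25 tested rose, 6 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.000843), Col6a2 by 0.55 ± 0.09, Il33, an alarmin cytokine, by 0.95 ± 0.14 and Cxcl1 by 0.61 ± 0.10, and Il6 fell (-0.73 ± 0.11). Acta2 (-0.49 ± 0.19, adjusted p = 0.401), Snai1 (-0.60 ± 0.13, adjusted p = 0.0833) and Mdm4 (0.37 ± 0.22, adjusted p = 0.565) did not pass the test. Of the genes called for p53 siRNA alone with TGF-beta, 473 of 808 (58.5%) moved the same way here, at a median ratio of 0.07, against 34.8% of genes not called, and the direction turned with DESeq2, 45.2% (ratio -0.04), and without replicate 1 of p53 siRNA with TGF-beta, 22.9% (ratio -0.19). Adjusted p was at most 0.047 for the genes given as changed, and rho with transcript length across genes was 0.40. The count of 70 fell to 5 and 13 without replicates 1 and 2 of the group with PRMT1 siRNA and to 11 and 1 without replicates 1 and 2 of the group with both siRNAs, but was 1962 with 15 libraries. Of the 11 genes named as changed, 1 kept the call without any 1 library of the comparison, Btg2, Col6a2, Ctgf, Cxcl1, Il33, Il6, Mdm2, Pmepa1, Sfrp1 and Smad7 being the exceptions.

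On the p53 siRNA background without TGF-beta, p53 targets were still higher with PRMT1 siRNA added, and cholesterol, matrix and some interferon genes were lower. With p53 also reduced, 853 genes were higher and 803 lower. Of the 1601 genes called for PRMT1 siRNA alone, 1532 (95.7%) moved the same way here, at a median ratio of 0.72, against 58% of genes not called. Of the p53 target genes, 20 of 42 tested rose and 2 fell (22 and 3 adjusted over the list alone, camera adjusted p = 1.4e-14). Cdkn1a rose from 9.12 ± 0.120 to 37.1 ± 0.715 CPM (2.02 ± 0.08), Pmaip1 by 1.20 ± 0.13, Ccng1 by 0.86 ± 0.08 and Sulf2 by 0.87 ± 0.09, and Trp53 itself rose by 0.71 ± 0.09. Among the cholesterol synthesis genes, 17 of 23 tested fell (18 adjusted over the list alone, camera adjusted p = 1.86e-34). Members included Insig1 at -1.32 ± 0.10. Among the fibroblast and collagen matrix genes, 13 of 30 tested fell (15 fell and 1 rose adjusted over the list alone, camera adjusted p = 3.39e-12). Members included Postn at -1.83 ± 0.10 and Lum at -1.86 ± 0.21. Among the interferon-stimulated genes, 15 of 32 tested fell (16 adjusted over the list alone, camera adjusted p = 3.63e-16, adjusted p = 0.123 with an estimated correlation). Members included Ifit2 at -1.97 ± 0.14. Among the G2/M phase genes, 20 of 31 tested rose (27 adjusted over the list alone, camera adjusted p = 2.86e-18). Members included Nusap1 at 0.64 ± 0.07 and Ndc80, a kinetochore gene, at 0.70 ± 0.09. Of the senescence-associated secretory genes, 8 of 21 tested rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 1.23e-06). Members included Cxcl1 at 1.23 ± 0.10 and Il6 at 1.01 ± 0.14. Ptgs2 rose by 1.88 ± 0.16 and Tnnt2 fell (-2.48 ± 0.24). Genes given as changed had adjusted p of 0.00104 or less, and rho with transcript length across genes was -0.28. The count of 1656 fell to 458 and 585 without replicates 1 and 2 of the group with p53 siRNA and to 522 and 691 without replicates 1 and 2 of the group with both siRNAs, and 15 libraries gave 4981. All 15 genes named as changed in this comparison kept their call whichever of its libraries was left out.

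With TGF-beta, PRMT1 siRNA on the p53 siRNA background lowered cholesterol and some amino acid stress genes and raised p53 target and epicardial genes, 846 genes being higher and 727 lower (945 and 1167 with DESeq2, 1375 and 1792 with length offsets). Of the 2427 genes called for PRMT1 siRNA alone with TGF-beta, 1875 (77.3%) moved the same way here, at a median ratio of 0.35, against 44.8% of genes not called, but 35.7% (ratio -0.5) without replicate 1 of p53 siRNA with TGF-beta. Of the cholesterol synthesis genes, 21 of 23 tested fell (23 adjusted over the list alone, camera adjusted p = 6.67e-74). Members included Idi1 at -1.60 ± 0.07, Cyp51 at -1.49 ± 0.07 and Insig1 at -1.54 ± 0.10. Of the unfolded protein and amino acid stress genes, 15 of 28 tested fell (20 adjusted over the list alone, camera adjusted p = 4.7e-11, adjusted p = 0.185 with an estimated correlation). Members included Asns at -0.78 ± 0.11 and Psat1 at -0.59 ± 0.08. Among the p53 target genes, 14 of 42 tested rose (14 rose and 4 fell adjusted over the list alone, camera adjusted p = 1.79e-06). Members included Eda2r at 1.67 ± 0.19, Pmaip1 at 1.25 ± 0.14 and Cdkn1a from 23.8 ± 1.25 to 47.6 ± 0.180 CPM. Trp53 stood at 90.0 CPM, against 66.5 with p53 siRNA alone. Among the epicardial and mesothelial genes, 12 of 25 tested rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 1.56e-10). Members included C3 at 0.95 ± 0.11, Msln at 0.92 ± 0.11, Gata6 at 0.50 ± 0.06 and Tbx18 at 0.52 ± 0.11. The secreted factor genes Ereg and Cxcl5 rose by 1.47 ± 0.15 and 1.39 ± 0.15 (of the senescence-associated secretory genes, 6 of 21 tested rose and 1 fell, 6 and 2 adjusted over the list alone, camera adjusted p = 0.000234, adjusted p = 0.0717 with an estimated correlation). Postn fell (-0.74 ± 0.09), Col1a1, type I collagen, (-0.60 ± 0.09), Jup (-0.77 ± 0.09), Snai1 (-0.55 ± 0.13) and Acta2 (-0.67 ± 0.19). With 15 libraries Acta2 no longer passed the test (adjusted p = 0.195). No adjusted p above 0.0463 belongs to a gene given as changed, and this contrast holds the library that stands apart (rho with transcript length across genes 0.36). Without that library 1788 genes were called, 986 shared with the 1573, against 8238 without its partner and 448 and 372 without replicates 1 and 2 of both siRNAs with TGF-beta. Of the 19 genes named as changed, 16 kept the call without any 1 library of the comparison, Acta2, Snai1 and Tbx18 being the exceptions.

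The TGF-beta response itself differed under PRMT1 siRNA for 322 genes, 201 more positive and 121 more negative, tested as the difference of the responses. Of the epicardial and mesothelial genes, 7 of 25 tested rose (9 adjusted over the list alone, camera adjusted p = 3.27e-08): Sfrp1 differed by 1.58 ± 0.12, Rspo1, a Wnt agonist, by 1.76 ± 0.18 and Gata6 by 0.76 ± 0.09, each falling less with PRMT1 siRNA. Among the cholesterol synthesis genes, 7 of 23 tested fell (13 adjusted over the list alone, camera adjusted p = 6.24e-11) relative to the control response, with Idi1 at -0.98 ± 0.10 and Lss, lanosterol synthase, at -0.68 ± 0.10. Of the fibroblast and collagen matrix genes, 4 of 30 tested rose (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000249, adjusted p = 0.105 with an estimated correlation) in relative terms, Fmod (1.01 ± 0.11) and Dcn (1.15 ± 0.19) falling less and Postn (0.89 ± 0.13) rising more. Of the G2/M phase genes, 3 of 31 tested fell (14 adjusted over the list alone, camera adjusted p = 1.84e-08). Members included Tpx2 at -0.50 ± 0.09. Mmp14 rose more with PRMT1 siRNA (0.84 ± 0.09), Igfbp3 (1.49 ± 0.14) and Clu (3.37 ± 0.27) fell less, and Ctgf (-0.77 ± 0.15), Cdkn1a (-0.64 ± 0.10) and the collagen gene Col7a1 (-2.53 ± 0.24) rose less. Bases differed: Postn stayed below control without and with TGF-beta, and Cdkn1a rose from 82.8 to 105 CPM, against 28.1 to 55.4. Acta2 (0.42 ± 0.27, adjusted p = 0.362), Snai1 (0.09 ± 0.19, adjusted p = 0.798) and Mdm4 (-0.58 ± 0.32, adjusted p = 0.297) did not pass the test. Every gene given as changed passed at an adjusted p of 0.0251 or less, and rho with transcript length across genes was -0.43. Leaving out any 1 of the 8 libraries lowered the count to between 55 and 143, and 15 libraries gave 4936. Of the 15 genes named as changed, 9 kept the call without any 1 library of the comparison, Cdkn1a, Ctgf, Dcn, Lss, Postn and Tpx2 being the exceptions.

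Under p53 siRNA the TGF-beta response differed for 158 genes, 70 more positive and 88 more negative. Of the interferon-stimulated genes, 9 of 32 tested fell (17 fell and 1 rose adjusted over the list alone, camera adjusted p = 4.58e-16, adjusted p = 0.403 with an estimated correlation) relative to the control response, Rsad2 (-1.43 ± 0.19), Ifit2 (-1.30 ± 0.20) and Cmpk2 (-1.16 ± 0.17). Cxcl1 (1.53 ± 0.15) and Cxcl5 (1.74 ± 0.21), which TGF-beta lowered in control cells, had more positive responses, as had Sfrp1 (1.14 ± 0.12), while Aldh1a1 (-0.84 ± 0.12) and Gpm6a (-1.01 ± 0.18) fell further. Acta2 gave 1.12 ± 0.27, adjusted p = 0.0813 and Tagln 0.94 ± 0.27, adjusted p = 0.131. Adjusted p was at most 0.0239 for the genes given as changed, and rho with transcript length across genes was -0.46. The contrast holds the library that stands apart: 361 genes were called without it, 7717 without its partner, and 29 to 71 without any 1 of the other 6 libraries. Of the 8 genes named as changed, 5 kept the call without any 1 library of the comparison, Cmpk2, Gpm6a and Ifit2 being the exceptions.

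The PRMT1 siRNA effect without TGF-beta was then compared between the p53 siRNA background and the control background. edgeR called 0 genes here, with 1192 at an unadjusted p under 0.05, DESeq2 called 52, and edgeR with 15 libraries called 1487. Trp53 differed by 0.65 ± 0.13, adjusted p = 0.221, and passed with 15 libraries (adjusted p = 0.00261), Cdkn1a by 0.46 ± 0.10, adjusted p = 0.311 and Id2 gave -0.92 ± 0.18, adjusted p = 0.218. As a set, cholesterol synthesis genes were lower on the p53 siRNA background (median log2 difference -0.24, camera adjusted p = 0.000191, adjusted p = 0.0375 with an estimated correlation). G2/M phase genes were higher (median 0.26, camera adjusted p = 3.23e-08, adjusted p = 0.0514 with an estimated correlation). The log2 differences correlated with transcript length across genes (rho -0.44).

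With TGF-beta the PRMT1 siRNA effect differed between the backgrounds for 118 genes, 70 more positive and 48 more negative with p53 siRNA (433 and 562 with DESeq2). Among the interferon-stimulated genes, 5 of 32 tested rose (17 rose and 1 fell adjusted over the list alone, camera adjusted p = 5.91e-10, adjusted p = 0.595 with an estimated correlation). Members included Oas2 at 2.27 ± 0.29, Rsad2 at 1.45 ± 0.19 and Cmpk2 at 1.10 ± 0.17. Gpm6a (1.71 ± 0.20), Lrrn4 (1.33 ± 0.19) and Aldh1a1 (0.83 ± 0.12) were more positive, and Sfrp1 (-1.15 ± 0.12), Saa3 (-4.50 ± 0.46), H19 (-1.86 ± 0.17) and the BMP-responsive Atoh8 (-1.32 ± 0.25) more negative. Mdm4 gave 0.76 ± 0.32, adjusted p = 0.162 (0.37, adjusted p = 0.163, without the library that stands apart, 1.33, adjusted p = 9.25e-06, without its partner), and Trp53 0.08 ± 0.13, adjusted p = 0.687. Genes given as changed had adjusted p of 0.0407 or less, and rho with transcript length across genes was 0.53. Here 372 genes were called without the library that stands apart, 8437 without its partner, and 8 to 48 without any 1 of the other 6 libraries. Of the 10 genes named as changed, 4 kept the call without any 1 library of the comparison, Aldh1a1, Atoh8, Cmpk2, Lrrn4, Oas2 and Rsad2 being the exceptions.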

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

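The mislabelling test, the tests of length bias in the reported genes and in 2 lists and the 4 tests of the siRNA mixture below were chosen after the result was seen, as were the fits of 15 libraries and with length offsets. The results here were picked out because the effect of 1 treatment differed between groups by a test of the difference.

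For 322 genes the TGF-beta response differed under PRMT1 siRNA. Log2 differences were Cdkn1a -0.64, Clu 3.37, Col7a1 -2.53, Ctgf -0.77, Dcn 1.15, Fmod 1.01, Gata6 0.76, Idi1 -0.98, Igfbp3 1.49, Lss -0.68, Mmp14 0.84, Postn 0.89, Rspo1 1.76, Sfrp1 1.58 and Tpx2 -0.50. Camera adjusted p was 1.84e-08 for the G2/M phase genes, 6.24e-11 for the cholesterol synthesis genes, 3.27e-08 for the epicardial and mesothelial genes and 0.000249 for the fibroblast and collagen matrix genes (0.105 with an estimated correlation). One technical explanation is a bias with transcript length, since these differences correlate with length. Of the 322 genes 94.1% stayed called with the same sign after the length trend was removed, at a median ratio of 0.92, which argues against it as their whole cause. Of the 4936 called with 15 libraries 59.3% did, between the bounds set beforehand, so for that wider set it cannot be told apart from an effect of PRMT1. For the epicardial and mesothelial genes (camera adjusted p = 4.18e-11 after length correction with 15 libraries) and the cholesterol synthesis genes (8.66e-16) the tests argue against it as well. A dependence on PRMT1, with or without TGF-beta, may hold for these genes and lists, as a hypothesis from the same data.

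For 158 genes the TGF-beta response differed under p53 siRNA, with log2 differences of Aldh1a1 -0.84, Cmpk2 -1.16, Cxcl1 1.53, Cxcl5 1.74, Gpm6a -1.01, Ifit2 -1.30, Rsad2 -1.43 and Sfrp1 1.14 and a camera adjusted p of 4.58e-16 for the interferon-stimulated genes (0.403 with an estimated correlation). For 118 genes the PRMT1 siRNA effect with TGF-beta differed on the p53 siRNA background, with log2 differences of Aldh1a1 0.83, Atoh8 -1.32, Cmpk2 1.10, Gpm6a 1.71, H19 -1.86, Lrrn4 1.33, Oas2 2.27, Rsad2 1.45, Saa3 -4.50 and Sfrp1 -1.15 and a camera adjusted p of 5.91e-10 for the interferon-stimulated genes (0.595 with an estimated correlation). Without TGF-beta the same difference was seen for lists, with a camera adjusted p of 3.23e-08 for the G2/M phase genes (0.0514 with an estimated correlation) and 0.000191 for the cholesterol synthesis genes.

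Both contrasts with called genes include replicate 2 of p53 siRNA with TGF-beta, which stands apart. Its log2 difference from its partner correlated with transcript length across genes at rho -0.58, past the bound set beforehand for loss of long transcripts (other groups reached 0.41, so the bound does not single it out); the shortest 20% of genes had a median of 0.59 and the longest -0.55 (control siRNA -0.16 and 0.17). Removing the trend lowered the root mean square difference only from 0.805 to 0.729, so loss of long transcripts may be a part of the cause and the rest, for which no biological explanation was tested, stays open. A wrong label is argued against: Trp53 was 73.6 CPM, below the lowest library without p53 siRNA (128), and Acta2 and Tagln lay above all 8 libraries without TGF-beta. RNA of another cell type met the bound set beforehand, a median over 0.5 for 1 of 3 marker lists: the cardiomyocyte markers reached 0.8 over 4 tested members; the evidence against it was looked for after that: of that list Tnnt2 gained 58.8 CPM and none of the other 15 markers more than 1.08, 1.84% of it, although cardiomyocytes would bring their other abundant transcripts.

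Trp53 was reduced less by the mixture of siRNAs than by p53 siRNA alone, by 0.71 ± 0.09 (log2) without and 0.44 ± 0.09 with TGF-beta. Weaker action of both siRNAs in the mixture is argued against, since Prmt1 differed from PRMT1 siRNA alone (-0.05 ± 0.16) without and -0.21 ± 0.16 with TGF-beta. A rise of Trp53 by PRMT1 siRNA alike on both backgrounds is argued against without TGF-beta, where the effects differed by 0.65 ± 0.13 (adjusted p = 0.221, and 0.00261 with 15 libraries). With TGF-beta the difference of 0.08 ± 0.13 met the condition set for this explanation, but it was 0.26 ± 0.09 with 15 libraries and 0.34 ± 0.07 (adjusted p = 0.0186) with length offsets as well, and -0.07 without replicate 1 of p53 siRNA with TGF-beta; agreement between both fits was asked for only after the first value was seen, and the explanation cannot be told apart from others. Weaker action of p53 siRNA alone, whose amounts are not given, could not be tested and stays open.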

How the results depend on the processing

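The fits of 15 libraries and with length offsets were chosen after seeing the data. DESeq2, RLE factors, no filter, the contrast groups only and the replicate block refit the same counts, so signs of named genes could hardly turn. Signs held in 314 of 314 values. Calls were lost for 56, 6, 10 and 1 with the contrast groups only, no filter, the block and RLE factors. Leaving out 1 library ended the call in 230 of 1428 values. With RLE factors no count of called genes moved by more than 1.5 times. Depth limits the tests to 15494 genes and excludes E-cadherin.

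Counts by edgeR with the groups of the contrast only were 9147 for TGF-beta under PRMT1 siRNA, 2207 for TGF-beta under p53 siRNA, 2700 for PRMT1 siRNA (untreated), 7650 for PRMT1 siRNA (TGF-beta), 726 for p53 siRNA (untreated), 0 for p53 siRNA (TGF-beta), 2435 for p53 siRNA on PRMT1 siRNA (untreated), 3020 for p53 siRNA on PRMT1 siRNA (TGF-beta), 4288 for PRMT1 siRNA on p53 siRNA (untreated), 0 for PRMT1 siRNA on p53 siRNA (TGF-beta), 4856 for the PRMT1 by TGF-beta interaction, 0 for the p53 by TGF-beta interaction, 108 for the PRMT1 by p53 interaction (untreated) and 0 for the PRMT1 by p53 interaction (TGF-beta). The 0 counts had 679, 1109, 1130 and 1969 genes at an unadjusted p under 0.05, where DESeq2 called 1526, 2112, 501 and 995. Without the filter they were 3882 for PRMT1 siRNA (TGF-beta), 609 for p53 siRNA (untreated), 3301 for p53 siRNA (TGF-beta), 1156 for p53 siRNA on PRMT1 siRNA (untreated), 586 for p53 siRNA on PRMT1 siRNA (TGF-beta), 2908 for PRMT1 siRNA on p53 siRNA (TGF-beta), 2128 for the PRMT1 by TGF-beta interaction, 1952 for the p53 by TGF-beta interaction, 461 for the PRMT1 by p53 interaction (untreated) and 3175 for the PRMT1 by p53 interaction (TGF-beta). DESeq2 gave 655 for p53 siRNA (untreated), 1526 for p53 siRNA (TGF-beta), 554 for p53 siRNA on PRMT1 siRNA (untreated), 225 for p53 siRNA on PRMT1 siRNA (TGF-beta), 832 for the PRMT1 by TGF-beta interaction, 501 for the p53 by TGF-beta interaction, 52 for the PRMT1 by p53 interaction (untreated) and 995 for the PRMT1 by p53 interaction (TGF-beta). The replicate block gave 60 for p53 siRNA on PRMT1 siRNA (untreated), 36 for p53 siRNA on PRMT1 siRNA (TGF-beta), 104 for the p53 by TGF-beta interaction, 1 for the PRMT1 by p53 interaction (untreated) and 75 for the PRMT1 by p53 interaction (TGF-beta); replicate numbers do not pair the libraries, since deviations from group means correlated at -0.4 to 0.25 over 28 group pairs, 6 of them over 0.1. Length offsets gave 3300 for PRMT1 siRNA (untreated), 3697 for PRMT1 siRNA (TGF-beta), 1258 for p53 siRNA (untreated), 1689 for p53 siRNA (TGF-beta), 756 for p53 siRNA on PRMT1 siRNA (untreated), 348 for p53 siRNA on PRMT1 siRNA (TGF-beta), 2997 for PRMT1 siRNA on p53 siRNA (untreated), 3167 for PRMT1 siRNA on p53 siRNA (TGF-beta), 1228 for the PRMT1 by TGF-beta interaction, 584 for the p53 by TGF-beta interaction, 42 for the PRMT1 by p53 interaction (untreated) and 517 for the PRMT1 by p53 interaction (TGF-beta). The 15 libraries gave 8150 for TGF-beta under PRMT1 siRNA, 7639 for TGF-beta under both, 4259 for PRMT1 siRNA (untreated), 6659 for PRMT1 siRNA (TGF-beta), 1877 for p53 siRNA (untreated), 3482 for p53 siRNA on PRMT1 siRNA (untreated), 1962 for p53 siRNA on PRMT1 siRNA (TGF-beta), 4981 for PRMT1 siRNA on p53 siRNA (untreated), 4936 for the PRMT1 by TGF-beta interaction, 361 for the p53 by TGF-beta interaction, 1487 for the PRMT1 by p53 interaction (untreated) and 372 for the PRMT1 by p53 interaction (TGF-beta). Length offsets with 15 libraries gave 8410 for TGF-beta under PRMT1 siRNA, 8031 for TGF-beta under both, 5107 for PRMT1 siRNA (untreated), 6127 for PRMT1 siRNA (TGF-beta), 2696 for p53 siRNA (untreated), 1256 for p53 siRNA (TGF-beta), 2981 for p53 siRNA on PRMT1 siRNA (untreated), 1851 for p53 siRNA on PRMT1 siRNA (TGF-beta), 5129 for PRMT1 siRNA on p53 siRNA (untreated), 2761 for PRMT1 siRNA on p53 siRNA (TGF-beta), 3787 for the PRMT1 by TGF-beta interaction, 718 for the p53 by TGF-beta interaction, 929 for the PRMT1 by p53 interaction (untreated) and 586 for the PRMT1 by p53 interaction (TGF-beta). Leaving out 1 library gave 4344 to 4620 for TGF-beta in control cells, 3080 to 3228 for TGF-beta under PRMT1 siRNA, 5082 to 10075 for TGF-beta under p53 siRNA, 3172 to 3501 for TGF-beta under both, 397 to 556 for PRMT1 siRNA (untreated), 692 to 797 for PRMT1 siRNA (TGF-beta), 55 to 127 for p53 siRNA (untreated), 148 to 8622 for p53 siRNA (TGF-beta), 4 to 9 for p53 siRNA on PRMT1 siRNA (untreated), 1 to 13 for p53 siRNA on PRMT1 siRNA (TGF-beta), 458 to 691 for PRMT1 siRNA on p53 siRNA (untreated), 372 to 8238 for PRMT1 siRNA on p53 siRNA (TGF-beta), 55 to 143 for the PRMT1 by TGF-beta interaction, 29 to 7717 for the p53 by TGF-beta interaction and 8 to 8437 for the PRMT1 by p53 interaction (TGF-beta). The 5 highest of these counts came without replicate 1 of p53 siRNA with TGF-beta, which leaves the library that stands apart alone in its group. The balance of higher against lower calls turned in at least 1 setting for 13 of 15 contrasts with called genes; with DESeq2 it turned for 5, among them PRMT1 siRNA with TGF-beta (1429 and 1447), p53 siRNA on PRMT1 siRNA with TGF-beta (123 and 102) and PRMT1 siRNA on p53 siRNA untreated (914 and 1049).

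The share of PRMT1 siRNA effects with the same sign on the p53 siRNA background was, without TGF-beta, 95.7% (ratio 0.72), 95.6% (ratio 0.68) with DESeq2, 96.6% (ratio 0.73) with replicate block, 80.7% (ratio 0.53) with 15 libraries, 94.2% (ratio 0.69) with length offsets, 87.3% (ratio 0.64) with both together, and 95.4% to 99.3% (ratios 0.72 to 0.78) leaving out 1 library. With TGF-beta it was 77.3% (ratio 0.35), 71.3% (ratio 0.29) with DESeq2, 80.6% (ratio 0.37) with replicate block, 87.1% (ratio 0.47) with 15 libraries, 80.9% (ratio 0.48) with length offsets, 86.9% (ratio 0.56) with both together, and 35.7% to 91.5% (ratios -0.5 to 0.5) leaving out 1 library. It reversed without replicate 1 of p53 siRNA with TGF-beta. For p53 siRNA effects on the PRMT1 siRNA background with TGF-beta it reversed with DESeq2 (45.2%, ratio -0.04) and without that replicate (22.9%, ratio -0.19), against up to 82.1% and 0.24 leaving out 1 library. No list or gene given in the text that changed sign was called in the reported fit. Of the lists given, the camera direction turned (adjusted p) for epicardial and mesothelial genes, p53 siRNA effect with TGF-beta (0.979 with length offsets) and senescence-associated secretory genes, p53 siRNA effect with TGF-beta (0.57 with 15 libraries, 0.457 with length offsets, 0.607 with length offsets and 15 libraries). Genes whose log2 change turned were Trp53, PRMT1 by p53 siRNA interaction with TGF-beta (-0.07 to 0.26 leaving out 1 library), Snai1, PRMT1 siRNA by TGF-beta interaction (-0.15 with length offsets, -0.14 with length offsets and 15 libraries, 0.00 to 0.19 leaving out 1 library), Mdm4, p53 siRNA effect without TGF-beta (-0.06 to 0.18 leaving out 1 library), Prmt1, p53 siRNA effect without TGF-beta (-0.23 to 0.06 leaving out 1 library), Snai1, p53 siRNA effect with TGF-beta (-0.02 with 15 libraries, -0.04 with length offsets and 15 libraries, -0.02 to 0.48 leaving out 1 library), Trp53, PRMT1 siRNA effect without TGF-beta (-0.04 to 0.14 leaving out 1 library) and Tjp1, TGF-beta response in control siRNA (-0.03 with length offsets, -0.03 with length offsets and 15 libraries, -0.04 to 0.22 leaving out 1 library).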

Other observations

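TGF-beta and the siRNAs also moved single genes of cell survival, oxygen response and arginine methylation, from lists that the report does not describe. Of the apoptosis regulators, 6 of 23 tested rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.428) with TGF-beta in control cells. Bcl2l11, which encodes the pro-apoptotic protein Bim, fell with TGF-beta under all 4 siRNA treatments (-1.44 ± 0.10 in control cells), and the anti-apoptotic Bcl2 rose by 0.76 ± 0.14. Among protein arginine methyltransferases, 6 of 10 tested rose (6 adjusted over the list alone, camera adjusted p = 0.196) with TGF-beta under p53 siRNA: Prmt1 by 0.59 ± 0.16 (0.24, adjusted p = 0.0747, without the library that stands apart, 0.87 without its partner), Prmt3 by 0.47 ± 0.10, Prmt5 by 0.43 ± 0.10 and Carm1 by 0.39 ± 0.08. Of the hypoxia and glycolysis genes, 6 of 26 tested rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000368, adjusted p = 0.448 with an estimated correlation) with PRMT1 siRNA on the p53 siRNA background with TGF-beta, Bnip3, a mitophagy receptor, by 0.92 ± 0.12. Of the endothelial markers, 2 of 6 tested rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.518) with TGF-beta in control cells; of the cardiomyocyte and haematopoietic markers 4 members each were tested, too few for camera. Bnip3, Bcl2l11, Bcl2 and the methyltransferase genes other than Prmt1 were chosen after their values were seen where the rule for names does not cover them.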
